A study of Mus musculus with 6 samples.

How the data were processed

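RNA was measured in 6 libraries of mouse bone marrow stromal cells (BMSCs), the adherent precursor cells of bone marrow that can form bone, fat and cartilage cells. Per the labels' protocols, the cells were differentiated towards osteoblasts for 7 days in a medium with 10% FBS, 50 µg/ml ascorbic acid and beta-glycerophosphate, which was replaced every 2 days. The medium held either conditioned medium from Hepa 1-6, a mouse hepatoma cell line, or control medium. Whether control medium was fresh or conditioned by other cells is not given in the sources used here. Effects of hepatoma factors and of conditioning by any cells can therefore not be told apart. Each group had 3 samples. Poly(A) RNA was isolated with oligo(dT) beads and sequenced as paired ends on an Illumina NovaSeq, per the labels' protocols. No source used here says whether the 3 samples of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

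The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 and the GRCm39 genome, with no role or order. One table of 56691 genes was deposited by the authors. Per the file headers, it holds a read count and an FPKM value for each gene and sample, the exonic length, the gene's position and its GO and KEGG terms. The deposited counts were whole numbers that were not normalized. The deposited FPKM values equalled the count divided by exonic length and by the sample's total count in 100% of cases, within a tolerance of 0.006 FPKM. The table held no row of unassigned reads, and 2639 genes had no symbol. Whether counting used strand is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart.

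The design fixed before the data were examined assumed that the table held FPKM only and named limma, with edgeR in its place if counts were found. Counts were found, so edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts was used, with TMM factors, group as the single term and Benjamini-Hochberg adjustment. Genes with a mean FPKM of at least 1 over the 6 samples were tested, which left 12153. A gene was called at an adjusted p under 0.05, and counted as changed at least 2-fold when its absolute log2 fold change was also at least 1. Log2 fold changes are conditioned minus control medium. Their standard errors (SE) were derived as the absolute unshrunk log2 fold change over the square root of the test's F statistic. For large folds on few counts, as in Arg1 with 17 control counts, such an SE can understate even the counting error. The total count per sample lay between 18661629 and 21329475. Genes named for their change that had 1 to 3 counts over a group are given as a ratio of counts scaled by library size, with an exact 95% counting interval. Where leaving out a library left 0 control counts, a floor of 3 counts over the other control libraries gave a lower bound. Intervals and floors cover counting error only.

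A set of 37 gene lists was fixed before the data were examined, with 544 different genes. Of these genes, 2 were found under another symbol, through the synonyms of a RefSeq gene table of the GRCm38.p6 assembly that was used for names only. The 32 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over these lists. The same test was run over 1402 GO and KEGG terms from the deposited table with 15 to 300 tested genes, with the tested genes as background. Counts of list members that rose or fell were also made adjusted over the list alone, and gave the same counts in 31 of the 37 lists.

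Genes named in the text were chosen by a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, without gene model numbers and pseudogenes. It adds 13 markers whatever their result, and up to 4 called members of each list with the largest change, or the 2 most abundant if none was called. A member that moved against most of its list could be named too. A further 7 gene lists, described among the other observations, were chosen after first results had been seen. The LXR and HIF lists were chosen before the values of their own members were seen. For these 7 lists 10 genes are named in addition, as are Alb, Rbp4, Apob, Krt8 and Hnf4a for the liver and hepatoma list. The values of 2 genes are not reported here.

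The same functions were tested on simulated data for the comparison of conditioned and control medium. Counts of 12153 genes were drawn with 200 genes changed by known folds. The edgeR test recovered 50% of 50 genes changed 1.2-fold, 81.6% of 49 genes changed 1.5-fold, 96% of 50 genes changed 2-fold and 98% of 50 genes changed 4-fold. Of its calls, 6.33% were false. Far fewer genes were changed in the simulation than the 5578 called in the measured data, so these shares need not carry over to those calls. Camera called all 3 lists that had been shifted and 1 of 37 lists that had not. The simulated genes were drawn independently, so this does not test camera's preset on correlated genes. In the measured data the macrophage list, for 1, had an estimated correlation of 0.35.

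Alternatives were other filters, other scalings, limma on log2(FPKM + 1) with several pseudocounts and variance settings, DESeq2 1.42.0, a replicate block, other list tests and leaving out each sample in turn. The planned pseudocount, centring, quantile, trend and weight alternatives belong to the limma fit and were run there. An alternative with protein-coding genes only was not run, since the table gives no gene type. Figures were drawn with matplotlib 3.10.9.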

Results

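The study compared the RNA of BMSCs after 7 days of osteoblast differentiation in Hepa 1-6 conditioned medium with that of cells in control medium, 3 samples in each group. The control libraries held 18661629, 20332530 and 20808829 counts in replicates 1 to 3. The conditioned medium libraries held 20820316, 19075341 and 21329475 counts. Between 22280 and 22962 genes had at least 1 count in a library. The 10 most abundant genes of each library took 7.63% to 7.82% of the counts in control medium and 6.67% to 6.74% in conditioned medium. The first principal component held 83.0% of the variance and separated the groups. Counts of replicates differed by more than sampling noise in every pair, with a chi-square per degree of freedom of 5.02 to 12.1 in control medium and 2.45 to 3.09 in conditioned medium, so each library was counted as 1 sample. FPKM values below are means ± SD with n = 3 per group, log2 fold changes are given ± SE, and adjusted p-values of genes are from edgeR's quasi-likelihood test.

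The comparison asked which transcripts differ when the cells differentiate in medium conditioned by hepatoma cells. Lcn2, which encodes the iron-carrier binding protein lipocalin 2, was at 0.773 ± 0.0850 FPKM in control medium and 277 ± 4.16 FPKM in conditioned medium, a 359-fold rise (adjusted p = 2.8e-26). Arg1, which encodes the arginine-cleaving enzyme arginase 1, was at 0.127 ± 0.0513 FPKM in control medium and 77.0 ± 5.79 FPKM in conditioned medium (log2 fold change 9.22 ± 0.13, adjusted p = 2.4e-22). The neutrophil chemokine gene Cxcl5 was at 0.0833 ± 0.0723 FPKM in control medium and 37.5 ± 1.17 FPKM in conditioned medium, and Csf3, which encodes granulocyte colony-stimulating factor, was at 0.107 ± 0.0404 FPKM in control medium and 23.1 ± 0.648 FPKM in conditioned medium. Among the falls, Cx3cr1, the fractalkine receptor gene of mononuclear phagocytes, was at 17.7 ± 1.84 FPKM in control medium and 0.490 ± 0.459 FPKM in conditioned medium, a 35.2-fold fall (adjusted p = 1.9e-14).

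Of 12153 genes tested, 2793 rose and 2785 fell, together 5578 or 45.9%. At least 2-fold changes were found in 642 genes, of which 377 rose and 265 fell. The groups did not overlap in 6464 tested genes, or 53.2%, where chance gives 10%. With FPKM rescaled to TPM and tested with limma, 38.6% of the calls were rises, against 47.0% with limma on log2(FPKM + 1) and 50.1% in the edgeR test. Lcn2 lies on chromosome 2 at 32274645 to 32278264 (GRCm39, minus strand), and Arg1 on chromosome 10 at 24791119 to 24803382, minus strand. Cxcl5 lies on chromosome 5 at 90907219 to 90909483, plus strand, near Cxcl3 at 90933962 to 90937459. Cx3cr1 lies on chromosome 9 at 119730682 to 119898945, minus strand. These positions are those of the whole genes as the table gives them.

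Apart from Lcn2, with 122 counts over the control libraries, the largest rises rested on few control counts. Arg1 had 17 counts over the control libraries, and Cxcl5 and Csf3 had 9 each. Cxcl3, another neutrophil chemokine gene, had 4 counts over the control libraries and 8969 over the conditioned medium libraries. Its fitted fold was 2021. Without control medium replicate 1 the other control libraries held 1 count, a ratio of 6075 (95% counting interval 1090 to 239978). Over each group, Wfdc21 had 405 counts against 1, a ratio of 400.0 (95% counting interval 71.4 to 15837). U90926 had 650 against 3, a ratio of 214 (72.9 to 1040). Rnase2a had 241 against 1, a ratio of 238 (42.3 to 9440), and Il23r, the interleukin 23 receptor gene, had 591 against 3, a ratio of 195 (66.3 to 946). Csta2 was at 0.370 ± 0.135 FPKM in control medium and 76.6 ± 8.30 FPKM in conditioned medium. Csta2 and Rnase2a belong to families of similar genes between which reads can be split, so their values are uncertain. The fitted fold of Cxcl5 was 298 without control medium replicate 3, against 450 with all samples. Without replicate 3 the ratio of U90926, on 1 control count, was 419 (75.02 to 16593). No control count remained for Wfdc21 without replicate 2 or for Rnase2a without replicate 3, and against a floor of 3 counts over the other 2 control libraries they were at least 88.1-fold and 51.8-fold higher in conditioned medium.

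Among the other large falls, Fcrls, an Fc receptor-like gene, was at 54.4 ± 1.23 FPKM in control medium and 2.05 ± 1.43 FPKM in conditioned medium (log2 fold change -4.70 ± 0.17). Hpgd, which encodes a prostaglandin-degrading dehydrogenase, was at 37.6 ± 1.41 FPKM in control medium and 1.72 ± 1.35 FPKM in conditioned medium. Cd207, the langerin gene, was at 5.12 ± 0.519 FPKM in control medium and 0.297 ± 0.184 FPKM in conditioned medium, and the myeloid receptor genes Treml4 and Clec4b1 changed by -3.54 and -3.50 on the log2 scale. The sulfotransferase gene Sult1a1, the oxysterol receptor gene Gpr183 and the cartilage matrix gene Comp changed by -3.89, -3.45 and -3.42. Conditioned medium replicate 1 held more Cx3cr1, Fcrls, Hpgd, Cd207 and Clec4b1 transcripts than replicates 2 and 3. Without it, the fold fall of Cx3cr1 became 77.2, against 35.2 with all samples, that of Fcrls 43.7 against 26.0, that of Hpgd 39.3 against 21.4, that of Cd207 25.4 against 16.6 and that of Clec4b1 18.2 against 11.3.

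Genes of osteoblast commitment fell as a group. Of 12 measured members of this list, 10 fell and 1 rose, with a median log2 fold change of -0.29 (camera adjusted p = 0.0083, and adjusted p = 0.12 with an estimated correlation). Sp7, the osteoblast transcription factor osterix, was at 6.77 ± 0.515 FPKM in control medium and 2.24 ± 0.560 FPKM in conditioned medium (log2 fold change -1.57 ± 0.12, adjusted p = 7.4e-10). The bone matrix gene Omd changed by -1.51 ± 0.090, the parathyroid hormone receptor gene Pth1r by -1.16 ± 0.093 and the homeobox gene Dlx5 by -0.58 ± 0.12. Falls of the most used markers were smaller. Runx2, the master transcription factor of osteoblasts, was at 5.12 ± 0.275 FPKM in control medium and 4.18 ± 0.366 FPKM in conditioned medium (log2 fold change -0.28 ± 0.068). Col1a1, the main bone collagen gene, was at 793 ± 39.8 FPKM in control medium and 641 ± 29.4 FPKM in conditioned medium (-0.29 ± 0.040). The phosphatase gene Alpl was at 30.6 ± 2.00 FPKM in control medium and 27.2 ± 1.25 FPKM in conditioned medium (-0.15 ± 0.052, adjusted p = 0.020). The Alpl call was lost without control medium replicate 1 (adjusted p = 0.083) and without conditioned medium replicate 2 (adjusted p = 0.13), and with limma without trend or with array weights (adjusted p = 0.076 and 0.063). The cadherin gene Cdh11 rose by 0.51 ± 0.040.

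Genes of mineralization moved apart. Of 6 measured members, 2 rose and 2 fell (median 0.025, camera adjusted p = 0.40). Ibsp, the bone sialoprotein gene, was at 19.9 ± 2.58 FPKM in control medium and 1.94 ± 0.770 FPKM in conditioned medium, a 10.0-fold fall. Spp1, the osteopontin gene, which macrophages also express, was at 318 ± 15.7 FPKM in control medium and 1335 ± 35.8 FPKM in conditioned medium, a 4.25-fold rise (log2 fold change 2.09 ± 0.042). Pdpn, the podoplanin gene, was at 4.42 ± 0.485 FPKM in control medium and 16.3 ± 0.857 FPKM in conditioned medium, and the pyrophosphate transporter gene Ank was at 11.4 ± 0.728 FPKM in control medium and 5.64 ± 0.305 FPKM in conditioned medium. Bglap, the osteocalcin gene, had 2 counts in each group, and Dmp1 had 2 counts in control medium and 12 in conditioned medium, a ratio of 5.93 (95% counting interval 1.32 to 54.5). Both lay below the expression filter. Sp7 lies on chromosome 15 at 102265041 to 102275617, minus strand, Ibsp on chromosome 5 at 104447037 to 104459335, plus strand, and Spp1 on chromosome 5 at 104582984 to 104588916, plus strand.

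**Figure D1:**
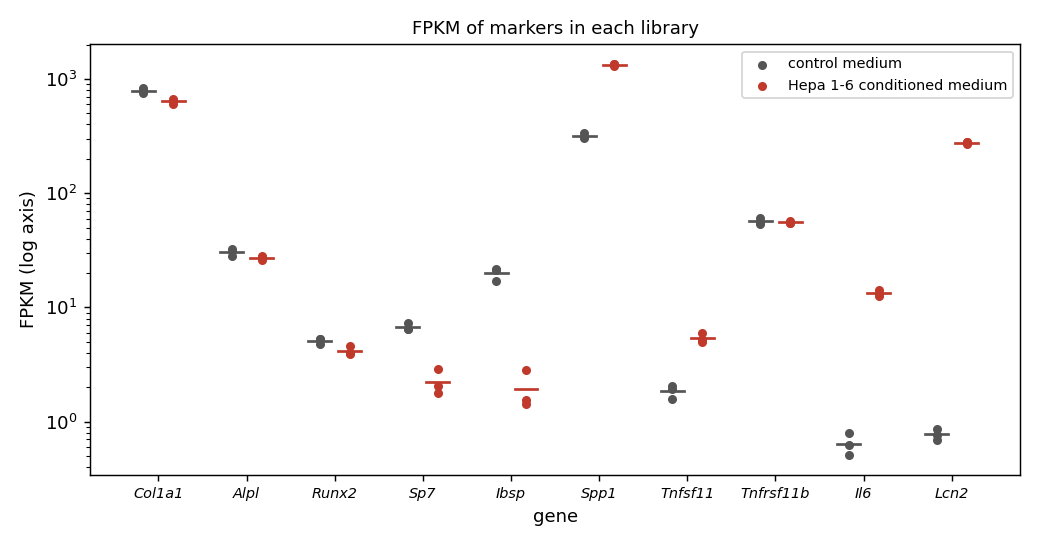
FPKM of 10 markers (log axis) in each library, with points for libraries and bars for group means of 3 samples. Spp1 has a mean of 318 FPKM in control medium and 1335 in conditioned medium, and Ibsp has means of 19.9 and 1.94.

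Inflammatory genes showed the strongest shift of any list tested. Of 20 measured cytokines and NF-kB targets, 17 rose and 1 fell, and the median log2 fold change was 3.79 (camera adjusted p = 7.4e-113). This was the single list still called with an estimated correlation (adjusted p = 0.0048). Saa3, an acute phase serum amyloid gene, was at 23.9 ± 1.39 FPKM in control medium and 2091 ± 57.6 FPKM in conditioned medium (log2 fold change 6.47 ± 0.052). The cytokine gene Il6 was at 0.643 ± 0.140 FPKM in control medium and 13.3 ± 0.861 FPKM in conditioned medium, a 20.7-fold rise (adjusted p = 5.8e-17). Relb, a subunit gene of NF-kB, fell by 0.28 on the log2 scale. Beside this rise, macrophage markers changed by a median of -0.49. Other myeloid lists rose: of 11 neutrophil and myeloid precursor genes only 4 were measured, with a median of 2.71. Inflammatory monocyte and macrophage genes, a list chosen after Arg1 had been seen, had a median of 2.86 without Arg1.

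Complement and acute phase genes rose as well, with 6 of 8 measured members up and 2 down (median 0.74, adjusted p = 1.7e-08, and adjusted p = 0.089 with an estimated correlation). Complement factor B, encoded by Cfb, rose by 4.26 ± 0.14 on the log2 scale, and C3 was at 13.4 ± 0.945 FPKM in control medium and 59.1 ± 2.15 FPKM in conditioned medium. The haptoglobin gene Hp rose by 1.62 ± 0.047 and the C1 inhibitor gene Serping1 by 1.05 ± 0.051. Of 4 measured neutrophil and myeloid precursor genes, 3 rose and 1 fell (median 2.71, adjusted p = 2.5e-09, and adjusted p = 0.054 with an estimated correlation). The rest of this list of 11 lay below the expression filter, so these values do not show a change of that cell type. The neutrophil collagenase gene Mmp8 was at 2.91 ± 0.405 FPKM in control medium and 84.3 ± 4.56 FPKM in conditioned medium. S100a8 was at 3.71 ± 0.936 FPKM in control medium and 24.5 ± 1.84 FPKM in conditioned medium, and its partner S100a9 at 1.95 ± 0.275 FPKM in control medium and 0.867 ± 0.458 FPKM in conditioned medium (-1.13 ± 0.41, adjusted p = 0.027). The S100a9 call was lost with DESeq2 (adjusted p = 0.054), without control medium replicate 2 (adjusted p = 0.075) and without conditioned medium replicate 2 or 3 (adjusted p = 0.12 and 0.093). The antimicrobial peptide gene Camp, with 13 control counts, rose by 2.69 ± 0.42.

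Of 20 measured type I interferon response genes, 13 rose and 4 fell, with a median of 0.26 (adjusted p = 0.026, and adjusted p = 0.53 with an estimated correlation). The deconjugase gene Usp18 rose by 1.07 ± 0.047, the transcription factor gene Irf7 by 0.94 ± 0.045 and Ifit1 by 0.79 ± 0.059. Ifit2, of the same family as Ifit1, was at 32.7 ± 4.14 FPKM in control medium and 9.57 ± 1.41 FPKM in conditioned medium (log2 fold change -1.76 ± 0.087). The list's call was lost without control medium replicate 1 (adjusted p = 0.056).

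**Figure D2:**
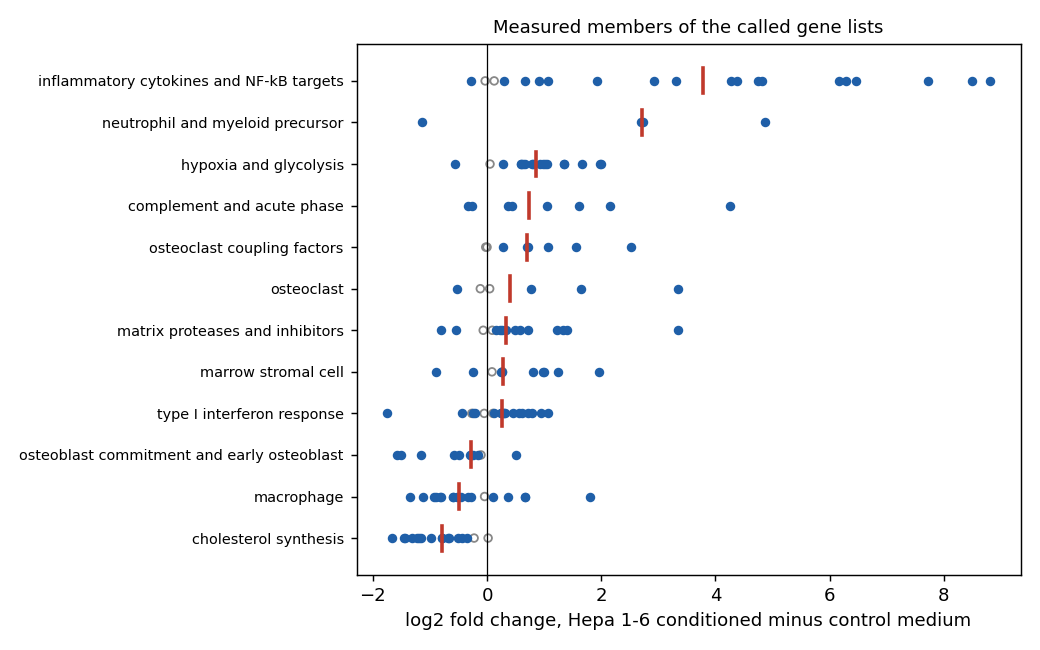
Log2 fold changes of the measured members of the 12 called lists, conditioned minus control medium. Filled points are genes with an adjusted p under 0.05, open points are other genes and red bars are list medians, which run from -0.79 for cholesterol synthesis to 3.79 for inflammatory cytokines and NF-kB targets.

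Macrophage transcripts were abundant in both groups and moved in both directions. Of 18 measured macrophage markers, 12 fell and 5 rose (median -0.49, adjusted p = 0.0060, and adjusted p = 0.53 with an estimated correlation). C1qa, a complement C1q subunit gene, was at 501 ± 29.4 FPKM in control medium and 261 ± 7.34 FPKM in conditioned medium. Csf1r, the receptor gene for macrophage colony-stimulating factor, was at 130 ± 1.34 FPKM in control medium and 50.4 ± 1.95 FPKM in conditioned medium, and Aif1 changed by -1.13 ± 0.071. The integrin gene Itgam was at 37.6 ± 1.17 FPKM in control medium and 129 ± 4.57 FPKM in conditioned medium (log2 fold change 1.80 ± 0.043). Of 6 measured osteoclast genes, 3 rose and 1 fell (median 0.40, adjusted p = 0.0049, and adjusted p = 0.12 with an estimated correlation). Acp5, the tartrate-resistant acid phosphatase gene, was at 27.3 ± 1.65 FPKM in control medium and 84.5 ± 2.69 FPKM in conditioned medium, and the gelatinase gene Mmp9 at 0.690 ± 0.0173 FPKM in control medium and 6.96 ± 0.460 FPKM in conditioned medium. Atp6v0d2 rose by 0.76 ± 0.14, and Nfatc1, the osteoclast transcription factor gene, changed by -0.53 ± 0.069. With limma on log2(FPKM + 1) the osteoclast list was not called (adjusted p = 0.22, and 0.19 to 0.21 with another pseudocount or quantile normalization).

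Factors that couple bone-forming cells to osteoclasts rose in 6 of 8 measured members and fell in 0 by edgeR (median 0.71, adjusted p = 7.2e-07, and adjusted p = 0.054 with an estimated correlation). Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, was at 1.85 ± 0.248 FPKM in control medium and 5.40 ± 0.490 FPKM in conditioned medium (log2 fold change 1.57 ± 0.13, adjusted p = 3.4e-09). Tnfrsf11b, which encodes its decoy receptor osteoprotegerin, was at 57.0 ± 3.34 FPKM in control medium and 55.5 ± 1.80 FPKM in conditioned medium (-0.022 ± 0.047, adjusted p = 0.74). The chemokine gene Ccl9 rose by 2.51 ± 0.042, the prostaglandin synthase gene Ptgs2 by 1.08 ± 0.057 and Sema3a by 0.72 ± 0.080. Tnfsf11 lies on chromosome 14 at 78514885 to 78545483, minus strand.

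Other cell type lists had few measured members. Of 11 platelet and red cell genes, 2 were measured and both rose: Pf4, a platelet chemokine gene, rose by 3.95 ± 0.051 on the log2 scale, and Ppbp rose by 5.32 ± 0.27. Both lie on chromosome 5 between Cxcl5 and Cxcl3, Ppbp at 90916377 to 90917922 and Pf4 at 90920294 to 90921242. The other members of the list lay below the expression filter, so these 2 rises do not show a change of that cell type. The basophil protease gene Mcpt8, the 1 measured member of its list, was at 1.49 ± 0.0458 FPKM in control medium and 18.8 ± 1.46 FPKM in conditioned medium. Of lymphocyte genes, Cd79b changed by -1.64 ± 0.24 and Cd4 by -0.74 ± 0.18, both falls. Of the 19 liver and hepatoma genes 1 was measured, Afp, at 1.34 ± 0.0781 FPKM in control medium and 1.42 ± 0.0833 FPKM in conditioned medium (0.099 ± 0.15, adjusted p = 0.63). The muscle actin gene Acta1, the 1 measured muscle gene, changed by -1.91 ± 0.20. Of 7 measured endothelial genes, 1 rose and 1 fell (median 0.11, adjusted p = 0.76), with Emcn at 0.40 ± 0.058 and Kdr at -0.45 ± 0.11.

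Marrow stromal genes rose in 7 of 11 measured members and fell in 2 (median 0.27, adjusted p = 4.4e-04, and adjusted p = 0.14 with an estimated correlation). Grem1, which encodes the BMP antagonist gremlin 1, was at 4.12 ± 0.298 FPKM in control medium and 15.9 ± 0.831 FPKM in conditioned medium. The growth factor receptor gene Pdgfra rose by 1.25 ± 0.060, the intermediate filament gene Nes by 0.99 ± 0.050 and Ly6a, the Sca-1 gene, by 0.98 ± 0.045. Of 15 measured matrix proteases and inhibitors, 11 rose and 2 fell (median 0.33, adjusted p = 2.9e-04, and adjusted p = 0.083 with an estimated correlation). Collagenase 3, encoded by Mmp13, was at 46.4 ± 1.15 FPKM in control medium and 115 ± 13.3 FPKM in conditioned medium, and the inhibitor gene Timp1 at 130 ± 15.1 FPKM in control medium and 338 ± 4.03 FPKM in conditioned medium. Adamts9 rose by 1.22 ± 0.11. Of 19 measured collagen and fibril assembly genes, 6 rose and 9 fell, or 10 fell adjusted over the list alone (median -0.078, adjusted p = 0.053). The proteoglycan gene Fmod was at 112 ± 1.02 FPKM in control medium and 40.5 ± 1.66 FPKM in conditioned medium, Col12a1 changed by -0.87 ± 0.055 and Postn by -0.79 ± 0.034, while Dcn rose by 2.05 ± 0.14.

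Glycolytic and hypoxia-responsive genes rose together. Of 18 measured members, 16 rose and 1 fell (median 0.87, adjusted p = 2.2e-18, and adjusted p = 0.054 with an estimated correlation). The lactate transporter gene Slc16a3 was at 5.02 ± 0.360 FPKM in control medium and 19.9 ± 0.476 FPKM in conditioned medium, and Adm, the adrenomedullin gene, at 14.6 ± 1.23 FPKM in control medium and 57.0 ± 2.52 FPKM in conditioned medium. The oxygen-sensing hydroxylase gene Egln3 rose by 1.67 ± 0.11 and the mitophagy gene Bnip3 by 1.35 ± 0.046, while Ndrg1 changed by -0.57 ± 0.070. Of 19 measured genes of oxidative phosphorylation and the TCA cycle, 6 rose and 0 fell by edgeR (median 0.044, adjusted p = 0.47), with Cycs at 0.59 ± 0.057, Mdh2 at 0.39 ± 0.046, Atp5b at 0.30 ± 0.043 and Cs at 0.22 ± 0.044. Of 13 mitochondrially encoded transcripts, 1 rose and 3 fell (median -0.027, adjusted p = 0.76). Values were 0.19 ± 0.042 for mt-Nd1, -0.17 ± 0.045 for mt-Nd5, -0.13 ± 0.041 for mt-Nd4 and -0.26 ± 0.051 for mt-Nd6, which is encoded on the opposite strand. The mt-Nd4 call was lost without control medium replicate 2 (adjusted p = 0.068) and without any 1 conditioned medium library (adjusted p = 0.055 to 0.070), and with limma without trend (adjusted p = 0.052). The mt-Nd1 call was lost with limma after quantile normalization (log2 fold change 0, adjusted p = 1). These transcripts took 1.86% to 2.07% of all counts in control medium and 1.93% to 1.99% in conditioned medium.

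Genes of cholesterol synthesis and uptake fell. Of 17 measured members, 15 fell and 0 rose by edgeR (median -0.79, adjusted p = 2.3e-10, and adjusted p = 0.089 with an estimated correlation). Idi1, an isomerase of the isoprenoid steps, was at 5.34 ± 0.185 FPKM in control medium and 1.67 ± 0.258 FPKM in conditioned medium (log2 fold change -1.66 ± 0.11). The sterol enzymes encoded by Cyp51 and Msmo1 changed by -1.46 ± 0.070 and -1.32 ± 0.061. Of 10 measured adipocyte genes, 3 rose and 5 fell (median -0.13, adjusted p = 0.28). Below the expression filter lay the rest of this list of 16, and bulk RNA cannot assign the measured transcripts to adipocytes. The lipoprotein lipase gene Lpl was at 118 ± 26.0 FPKM in control medium and 35.3 ± 0.930 FPKM in conditioned medium, Plin4 changed by -1.61 ± 0.12 and the transcription factor gene Cebpa by -1.14 ± 0.057, while the fatty acid carrier gene Fabp4 was at 9.20 ± 0.200 FPKM in control medium and 22.8 ± 1.16 FPKM in conditioned medium. Pparg, the adipocyte master regulator, was at 9.11 ± 0.824 FPKM in control medium and 7.02 ± 0.492 FPKM in conditioned medium (-0.36 ± 0.081, adjusted p = 9.9e-04).

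Of 16 measured growth factors and IGF binding proteins, 7 rose, or 8 adjusted over the list alone, and 6 fell. The median of this list was 0.19 while camera's direction was down (adjusted p = 0.46). Igf1 was at 41.5 ± 2.62 FPKM in control medium and 8.75 ± 1.11 FPKM in conditioned medium, and the binding protein genes Igfbp2 and Igfbp5 changed by -1.77 ± 0.089 and -1.54 ± 0.060, while Angptl4 rose by 1.85 ± 0.082. Of 10 measured Wnt targets and antagonists, 4 rose and 4 fell, with a median of -0.15 and camera's direction up (adjusted p = 0.76). The secreted Wnt antagonist genes Sfrp4, Sfrp2 and Sfrp1 rose by 3.14 ± 0.13, 2.16 ± 0.15 and 1.05 ± 0.050, and the Wnt-induced gene Nkd1 changed by -1.79 ± 0.14. Of 8 measured BMP targets, 4 fell and 0 rose by edgeR (median -0.13, adjusted p = 0.40), with Id1 at -0.65 ± 0.083, Smad6 at -0.48 ± 0.083, Id4 at -0.21 ± 0.068 and Id3 at -0.17 ± 0.050. The Id4 call was lost without conditioned medium replicate 2 (adjusted p = 0.12) and the Id3 call without conditioned medium replicate 3 (adjusted p = 0.057). Of 16 measured TGF-beta targets and contractile genes, 2 rose and 7 fell (median -0.076, adjusted p = 0.27), with Skil at -0.81 ± 0.049, Tgfbi at -0.48 ± 0.055, Itga11 at -0.36 ± 0.046 and Nox4 at -0.34 ± 0.093.

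Of 5 measured Notch pathway genes, 3 rose, or 4 adjusted over the list alone, and 1 fell (median 0.19, adjusted p = 0.43). Notch1 was at 0.48 ± 0.061, Jag1 at 0.34 ± 0.051, Notch3 at 0.19 ± 0.066 and Hes1 at -0.29 ± 0.11 on the log2 scale. The Hes1 call was lost with DESeq2 (adjusted p = 0.054), with limma without trend (adjusted p = 0.055) and without control medium replicate 2 (adjusted p = 0.17) or conditioned medium replicates 2 and 3 in turn (adjusted p = 0.095 and 0.12). The Notch3 call was lost without control medium replicate 1 (adjusted p = 0.13) or conditioned medium replicates 1 and 2 in turn (adjusted p = 0.070 and 0.090), and in all 8 limma fits (adjusted p = 0.051 to 0.20). Of 6 measured chondrocyte genes, 1 rose and 3 fell, with a median of 0.0084 and camera's direction down (adjusted p = 0.12). Col11a1 was at 72.0 ± 2.51 FPKM in control medium and 36.2 ± 1.30 FPKM in conditioned medium, Prg4 rose by 1.02 ± 0.14 and Col2a1 was at -0.12 ± 0.043, a call lost without control medium replicate 1 or 2 (adjusted p = 0.067 and 0.053) without conditioned medium replicate 1 or 3 (adjusted p = 0.14 and 0.12), with no filter (adjusted p = 0.065) and with limma without trend (adjusted p = 0.051).

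Of 15 measured NRF2 and oxidative stress genes, 6 rose and 7 fell, with a median of -0.088 and camera's direction up (adjusted p = 0.32). The mitochondrial superoxide dismutase gene Sod2 was at 7.70 ± 0.255 FPKM in control medium and 30.1 ± 0.259 FPKM in conditioned medium and the metallothionein gene Mt2 rose by 1.78 ± 0.12. Gclm, a subunit gene of the enzyme that starts glutathione synthesis, was at 60.0 ± 2.67 FPKM in control medium and 16.6 ± 1.66 FPKM in conditioned medium, while the cystine transporter gene Slc7a11 rose by 1.37 ± 0.056. Slc7a11 also belongs to the integrated stress response list, where 5 of 16 measured genes rose and 6 fell, or 7 fell adjusted over the list alone, with a median of -0.0097 and camera's direction up (adjusted p = 0.86). In this list Chac1 changed by -1.06 ± 0.12, Slc7a5 by -0.72 ± 0.054 and Cebpb by 0.92 ± 0.076. Of 14 measured unfolded protein response genes, 6 rose and 1 fell (median 0.040, adjusted p = 0.27), with Pdia4 at 0.99 ± 0.042, Manf at 0.41 ± 0.050, Calr at 0.36 ± 0.040 and Herpud1 at -0.35 ± 0.054. Of 9 measured heat shock genes, 4 rose and 2 fell (median 0.078, adjusted p = 0.46), with Hspd1 at 0.52 ± 0.044, Hsp90aa1 at 0.41 ± 0.042, Hspb1 at -0.45 ± 0.073 and Hspa1b at -0.43 ± 0.11.

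Of 18 measured mitosis genes, 9 fell and 1 rose, or 2 rose adjusted over the list alone (median -0.14, adjusted p = 0.40), with Ccnb2 at -0.51 ± 0.098, Ccna2 at -0.35 ± 0.061, Kif11 at -0.32 ± 0.067 and Bub1b at -0.28 ± 0.075. Of 18 measured DNA replication genes, 4 rose and 6 fell (median -0.012, adjusted p = 0.58), with Ccne1 at 0.75 ± 0.081, Pcna at -0.54 ± 0.046, Mcm5 at -0.53 ± 0.065 and Mcm6 at -0.44 ± 0.048. Of 14 measured p53 targets and senescence genes, 4 rose and 5 fell, or 6 fell adjusted over the list alone (median -0.023, adjusted p = 0.41), with Sesn1 at -1.54 ± 0.056, Bbc3 at -0.56 ± 0.15, Ckap2 at 0.53 ± 0.073 and Mdm2 at 0.42 ± 0.041. Of 12 measured immediate early genes, 4 rose and 6 fell, with a median of -0.24 and camera's direction up (adjusted p = 0.86), and with Ier3 at 1.69 ± 0.058, Atf3 at -0.57 ± 0.049, Nr4a1 at -0.55 ± 0.13 and Klf2 at -0.54 ± 0.10.

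Of the 32 lists tested, camera called 9 up and 3 down, and 1 with an estimated correlation. Among 1402 annotation terms, 95 were called up and 6 down. With an estimated correlation camera called 0 terms, 105 having an unadjusted p under 0.05, and fry called 860. Chemokine-mediated signalling led, with 17 of 19 genes up and 1 down (median log2 fold change 3.68, camera adjusted p = 3.0e-106). In neutrophil chemotaxis 25 of 49 genes rose and 10 fell (adjusted p = 4.3e-35), in the response to interleukin 1 28 of 54 rose and 11 fell (adjusted p = 1.8e-18) and in the IL-17 pathway 34 of 67 rose and 12 fell (adjusted p = 5.1e-17). The glycolytic process had 31 of 38 genes up and 1 down (adjusted p = 1.2e-07), and the HIF-1 pathway 53 of 112 up and 17 down (adjusted p = 0.00032). Cholesterol biosynthesis had 18 of 24 genes down and 0 up (median -0.44, adjusted p = 3.5e-06). Camera on log2(FPKM + 1) called 37.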

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

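The comparisons with DESeq2, RLE factors, library totals, filterByExpr and limma on log2(FPKM + 1) were chosen after seeing the data, the others before. The count of changed genes lay within 1.5 times of 5578 under every alternative run, from 3829 with a mean FPKM of at least 5 to 6421 with filterByExpr, and DESeq2 called 5028, of which 5026 were shared. The count of at least 2-fold changes (642) became 1384 with no filter, 1180 with filterByExpr and 315 with a mean FPKM of at least 5, where other numbers of genes were tested. With limma on log2(FPKM + 1), whose pseudocount shrinks the folds of low genes, it was 420, and within that fit 420 when median-centred, 414 with quantile normalization, 418 without trend and 421 with array weights. A pseudocount of 0.1 gave 628. The 12 called lists became 1 with an estimated correlation and 26 with fry, which tests another hypothesis. The 101 called terms became 0 with an estimated correlation (105 at an unadjusted p under 0.05), 860 with fry, 37 with limma on log2(FPKM + 1), 36 with a pseudocount of 0.1 and 33 with quantile normalization; the cause of the last 3 was not tested. Leaving out each sample in turn gave 4769 to 5873 changed genes, 629 to 664 with at least 2-fold changes, 12 to 13 lists and 96 to 102 terms. Of 161 named genes tested, 152 kept their direction and their side of the threshold under all 22 alternatives in which they were tested. Direction turned in none of the named genes or called lists. The samples share only a number across groups: deviations of same-numbered samples correlated by -0.0042, 0.039 and 0.051. With a replicate block, 5662 genes changed, 639 at least 2-fold, and 13 lists and 105 terms were called. Depth limits genes such as Wfdc21 and Rnase2a, with 1 control count each.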

Other observations

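Except for the tests of other splits of the samples, the tests in this part were chosen after first results were seen, those of the LXR and HIF lists before the values of their members were seen. Genes of inflammatory monocytes and macrophages, a list of 14 chosen after Arg1 had been seen, rose in 11 of 12 measured members. Without Arg1, 10 of 11 rose (median log2 fold change 2.86, camera adjusted p = 3.5e-68, and adjusted p = 0.0042 with an estimated correlation). Nos2, the inducible nitric oxide synthase gene, was at 0.157 ± 0.131 FPKM in control medium and 11.2 ± 1.98 FPKM in conditioned medium, a 72.6-fold rise that became 113-fold without control medium replicate 1. Arg1 and Nos2, which encode enzymes that use the same amino acid, thus rose together. Of 11 measured genes of resident-type macrophages, a list of 13 chosen after Cx3cr1 and Fcrls had been seen, 8 fell and 2 rose. Without Cx3cr1 and Fcrls, 6 of 9 fell and 2 rose (median -0.44, adjusted p = 9.8e-06, and adjusted p = 0.030 with an estimated correlation). Because these lists were drawn up with the pattern in view, their p-values are not independent evidence of it. Vsig4, a complement receptor gene, was at 11.9 ± 0.724 FPKM in control medium and 2.24 ± 0.508 FPKM in conditioned medium.

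Of 42 measured proteasome genes, 16 rose and 0 fell by edgeR (median 0.11, camera adjusted p = 0.21). Of 81 ribosomal protein genes, 2 rose and 10 fell (median -0.048, adjusted p = 0.30). Of 7 MHC class II genes 2 were measured, H2-DMa and H2-DMb1, with log2 values of -0.12 ± 0.14 and 0.047 ± 0.11 (adjusted p = 0.50 and 0.75).

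The rise of inflammatory cytokines and NF-kB targets could reflect a higher share of macrophages, but the macrophage list had a median log2 fold change of -0.49, and its largest rise, 1.80 for Itgam, lay below the cytokine median of 3.79. Carried-over Hepa 1-6 cells would bring abundant liver transcripts, but Alb had 1 count over each group, and the 18 list members other than Afp gained 0.960 CPM (SE 0.350), or 0.0120% of the 8011 CPM that the cytokine list gained. This measure was added after the ratio of summed CPM in conditioned over control medium had been seen. That ratio was 1.22 over all 19 members, most of whose counts were Afp. Without Afp it was 1.84, above the bound of 1.5 first set. Rbp4 went from 29 counts in control medium to 81 in conditioned medium, and Apob from 15 to 28. Krt8 and Hnf4a had 0 counts in each group. If Hepa 1-6 cells express the list's genes, these values argue against carry-over as the source of the cytokine gain. No Hepa 1-6 profile was used here to check that, and a small carry-over stays open. After the trend of fold change on GC content and length was removed, the cytokine median was 3.77. A response of the cells to the conditioned medium and the arrival or survival of a myeloid subtype that is richer in these transcripts stay open, and bulk RNA cannot assign the transcripts to a cell type.

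The fall of early osteoblast genes could come from a lower share of stromal cells. For falls of over 2-fold, as in Sp7, Omd and Pth1r, a lower share of all stromal cells would need collagen genes to fall alike. A shift between kinds of stromal cells was not tested and stays open. The collagens measured in the collagen list ran from -0.87 for Col12a1 to 0.15 for Col3a1. The lower quartile of all 19 measured members was -0.60, and 1 of them, Fmod, fell at least 2-fold. Of these members 9 fell and 6 rose. The risers include enzymes such as P4ha1 (0.60), so the list's median and quartiles can understate a fall of matrix genes. For the smaller falls, as in Runx2 and Col1a1, the collagen and contractile lists together had a median of -0.078 with quartiles of -0.44 and 0.089, while the marrow stromal list had a median of 0.27 with quartiles of 0.16 and 0.98. Stromal lists thus moved apart, and a small change in share and a change within the cells cannot be told apart. GC content and length left the list's median at -0.28 after their trend was removed, and a change of transcription in response to the conditioned medium stays open as a hypothesis.

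Cx3cr1 was at 4.67 CPM in conditioned medium replicate 1 and at a mean of 1.03 in replicates 2 and 3. Over 40 genes at least 4-fold higher in control medium, replicate 1 lay off the other replicates by a median of 4.28% of the gap between the groups (SE 0.88, over genes, which are not independent), and 36 of the genes lay towards control. If control RNA or reads were mixed into that library, genes that rose should show a like share: over 126 genes at least 4-fold higher in conditioned medium the median was 3.33% (SE 1.36), but replicate 3 lay at -3.77% in the same measure. Because of this spread between libraries, a criterion added after the values were seen, mixing cannot be told apart from a slightly weaker response in that sample. Without this library 4913 genes were called, and 664 changed at least 2-fold.

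A hypothesis that the rise of glycolytic genes is part of a wider HIF programme was tested on 14 HIF targets outside glycolysis, whose members were fixed before their values were seen. Of 13 measured, 9 rose and 2 fell, with a median of 0.54 (camera adjusted p = 5.2e-06, and adjusted p = 0.021 with an estimated correlation). This met the bound set beforehand, that most measured members rise and the median lies above 0. The first list had already shown rises of hypoxia-responsive genes outside glycolysis, such as Adm, Egln3 and Bnip3. Meeting the bound was thus likely in advance and adds little. The adjustment included the macrophage lists drawn up with the pattern in view, so these p-values cannot be set against those of the fixed lists. Hilpda, a lipid droplet gene, was at 4.81 ± 0.725 FPKM in control medium and 24.8 ± 1.49 FPKM in conditioned medium, Pfkfb3, which itself regulates glycolysis, rose by 2.16 ± 0.051 and Fam162a by 1.38 ± 0.080. Oxygen was not measured, and HIF induced by inflammatory signals stays open. A second hypothesis, that cholesterol synthesis genes fell because the cells were loaded with sterol, predicts a rise of LXR targets. Of 8 measured, 2 rose and 4 fell, with a median of -0.18 and quartiles of -0.54 and 0.13, which meets the bound set beforehand against the hypothesis (a median below 0 and more falls than rises). The quartiles span 0, a criterion added after the values were seen, so the list did not decide it. Abca1, a cholesterol exporter gene, rose by 0.71 ± 0.052, while Smpdl3a changed by -0.84 ± 0.047 and Nr1h3, the LXR alpha gene, by -0.68 ± 0.082.

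The 6 samples can be split in 10 ways into 3 and 3, too few for a share under 0.05. The real split, 1 of 10 to reach its counts, gave 5578 genes, 642 of them at least 2-fold, 12 lists and 101 terms. The highest counts among the other 9 splits were 0 genes by edgeR, with at most 226 at an unadjusted p under 0.05, 0 genes at least 2-fold, 7 lists and 24 terms. Each of these 9 splits mixes both media in each group, so the difference between media counts as spread within groups. Low gene counts there followed from the design and are not a measure of how many of the 5578 calls are false.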
